A study of Anguilla anguilla with 15 samples.

How the data were processed

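Gonad RNA of European eels (Anguilla anguilla) from 2 sites, Certes and Gironde, was compared on 2-colour microarrays. There were 15 arrays, 8 from Certes and 7 from Gironde. Per the labels' protocols, cDNA of each sample was labelled with Cy3 and hybridised together with cDNA of a common reference labelled with Cy5. The reference was a pool of gonads from 30 wild Certes eels, so it is no sample of either group, and no array had its dyes swapped. A preference of one dye for a given contig therefore enters every ratio, and it drops out of the difference between the sites only where all arrays share one scale. Whether they did was not measured. Slopes of the arrays on the mean of the other arrays averaged 1.06 in Gironde (0.956 to 1.18) and 0.94 in Certes (0.819 to 1.06). Such slopes do not separate array scale from real distance to the pool, so a dye preference may remain in the differences. The contigs are assembled transcript sequences. Neither data table pairs their IDs with gene names, and 0 of the 992 IDs occur in the gene table used here, which holds 31451 genes of the eel reference assembly.

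The values analysed are the authors' processed log2 ratios, 1 per contig and array, in a deposited table whose columns carry the sample identifiers. Image analysis, background correction, treatment of repeated spots, filters and normalization are not given in the sources used here. Every array's median was 0 in the table, so the arrays had been centred on their medians, and 121 of the 14880 cells were empty. The log base and the direction of the ratio are not stated with the table. They were taken as log2 of sample over reference, which is likely and not certain. The basis for the direction is that the reference pool's brightness and the mean log ratio were negatively correlated across contigs (Spearman's rho -0.35; contigs are not independent replicates), on each of the 15 arrays. If the table held reference over sample, log ratios and differences would change sign, and higher would exchange with lower and above the pool with below it in every count and share. The sizes of differences, the SDs, the p-values, the number of contigs past a threshold and the correlations of difference with level would stay. A base of 10 is hard to reconcile with values between -10.9 and 9.99. If the base were e, a log2 change printed here would be a larger fold.

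A second deposited table holds the scanner's foreground and background intensity of 2976 spots, 3 per contig, for the reference and the sample channel of 15 slides. Its slides are numbered and the numbers match no label of a single sample, so 59 of its columns were not used. The remaining column, the foreground intensity of the reference channel on slide 1, was used only to rank contigs by brightness in the reference pool (median of the 3 spots). An average of the sample channels over all slides was looked at while the tables were being examined and enters no result. How far each spot stood above its background on a given sample's array is therefore unknown here, and the number of arrays limits the precision.

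The sites were compared per contig with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, no covariate) on all 15 arrays, with at least 2 values per site required, which removed no contig. P-values were adjusted by Benjamini-Hochberg over the 992 contigs, with a threshold of 0.05. Whole-profile values were computed on the 921 contigs with a value on all arrays in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). They were the share of the squared distance between arrays that lay between the sites, and each array's root mean square distance per contig to the mean of its own site, multiplied by the square root of n/(n - 1). These, the SD of the log ratios per array, the slope of each array on the mean of the other arrays and the number of empty cells were tested with exact permutation tests over all 6435 splits into 8 and 7 arrays. All were two-sided except the share between the sites, which was one-sided. In the test of spread, each array's distance was taken once, to the mean of its real site, and these distances were regrouped. Site means were not recomputed for each split, so p-values of the spread are approximate although all splits were counted. The labels give each sample a code of its own but do not say in words that each came from a different eel, so p-values measure the spread between these samples.

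The test, the samples, the alternatives and the rule for naming genes were fixed before the data were examined, and several had to be changed. The plan was to start from scanner intensities with background correction and loess, and that start was replaced by the authors' table. A test of the reference channel between the sites and alternatives of background correction, normalization within the array, the Cy3 channel alone, a filter on spots above background and the slide as a block were not run. The reason is that slide numbers match no sample label, and slides were not matched to samples by their values. The 22 gene lists (oocyte, yolk uptake, steroid synthesis, stress, xenobiotic, immune and other cell type markers among them) had 0 matched members, so no list was tested. Of the contigs the naming rule chose, only the 2 higher and the 2 lower in Gironde with the smallest p are named, since an ID without a gene says little. The per-array comparisons of SD, slope and empty cells were added after the values were seen. Alternatives run were 2 scalings between arrays, array quality weights, a test with unequal variances, a variance trend with robust settings, contigs above the median brightness of the reference, complete contigs only, other thresholds and leaving out each array.

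The limma step was tested on simulated data with the real contigs' means and within-site SDs and 200 contigs changed. Of 50 contigs changed by 1 on the log2 scale, 74% were called, of 50 changed by 2, 96% were called, and of 50 changed by 0.5, 30% were called, while 6 of 792 unchanged contigs were called. These simulated contigs varied independently and equally in both sites. With 200 of 992 contigs changed, the Benjamini-Hochberg cutoff is looser than where few contigs change. The shares called therefore do not carry over to data with few changes. The permutation tests were tested on 20 simulated data sets of each kind. With the spread of 1 site doubled and no shift, the spread test called 20 of 20 and the test of the share between the sites called 7 of 20. With equal spread and no shift they called 0 and 2 of 20. The test of the share may therefore also respond to unequal spread, though a doubling is larger than the excess found here.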

Results

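Gonadal transcript levels were measured in female European eels from a site described as clean, Certes, and from a site described as contaminated, Gironde. The title of the series places the animals in artificial gonad maturation, and the labels give no stage for single animals. The array carried 992 contigs, and 8 Certes and 7 Gironde samples were each hybridised against the same pool of gonads from wild Certes eels. Each array gave a value for 953 to 991 contigs. The question the design poses is which transcripts differ between the gonads of eels from the 2 sites.

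Many contigs stood apart from the pool in the same direction in both sites. At least 2-fold above the pool (1 on the log2 scale) in both site means were 217 contigs, and at least 2-fold below it in both were 199. No contig lay 2-fold above the pool in the mean of one site and 2-fold below it in the other (0 contigs). Site means ranged from -9.13 to 6.84 on the log2 scale. Single arrays of different sites correlated with a median Pearson r of 0.900 over 56 pairs (across contigs, which are not independent replicates). That value lay between the medians within Certes, 0.920 over 28 pairs, and within Gironde, 0.891 over 21 pairs. The same pool and dyes are in every one of these arrays, which adds to all 3 values. The levels include any preference of a dye for a contig, and the pool's own variation was not measured. They also include any difference in maturation between the pool's wild eels and the animals sampled, which was not examined here.

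Between the sites, 1 of 992 contigs passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, contig_31845, and it was lower in Gironde. Its log2 ratio to the pool was -5.38 ± 0.96 (SD, n = 7) in Gironde and -3.38 ± 0.51 (SD, n = 8) in Certes. The difference was -1.996 ± 0.36 (SE; limma, adjusted p = 0.0388), with a 95% interval from -2.76 to -1.23. All 7 Gironde arrays lay below all 8 Certes arrays. The contig was dimmer than the median contig in the reference pool (log2 brightness 7.85 against 7.95). Read as sample over reference, its ratios put the samples far below that dim pool signal in both sites. The samples' signal may thus be near background, which was not examined here, so the size of the difference is uncertain. The call was lost with arrays scaled to an equal median absolute deviation, where the difference was -1.38 (limma, adjusted p = 0.38), and with arrays scaled to an equal SD, where it was -1.40 (limma, adjusted p = 0.179). At the same difference, a test with unequal variances gave an adjusted p of 0.291. It was also lost in 10 of the 15 fits that left out 1 array (Certes 1, 2, 4, 5, 6 or 8, or Gironde 1, 3, 5 or 6), where the adjusted p of limma reached 0.116. Of 100 splits of the 15 arrays into 8 and 7, the real one included, 6 gave at least 1 contig past the threshold.

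**Figure D1:**
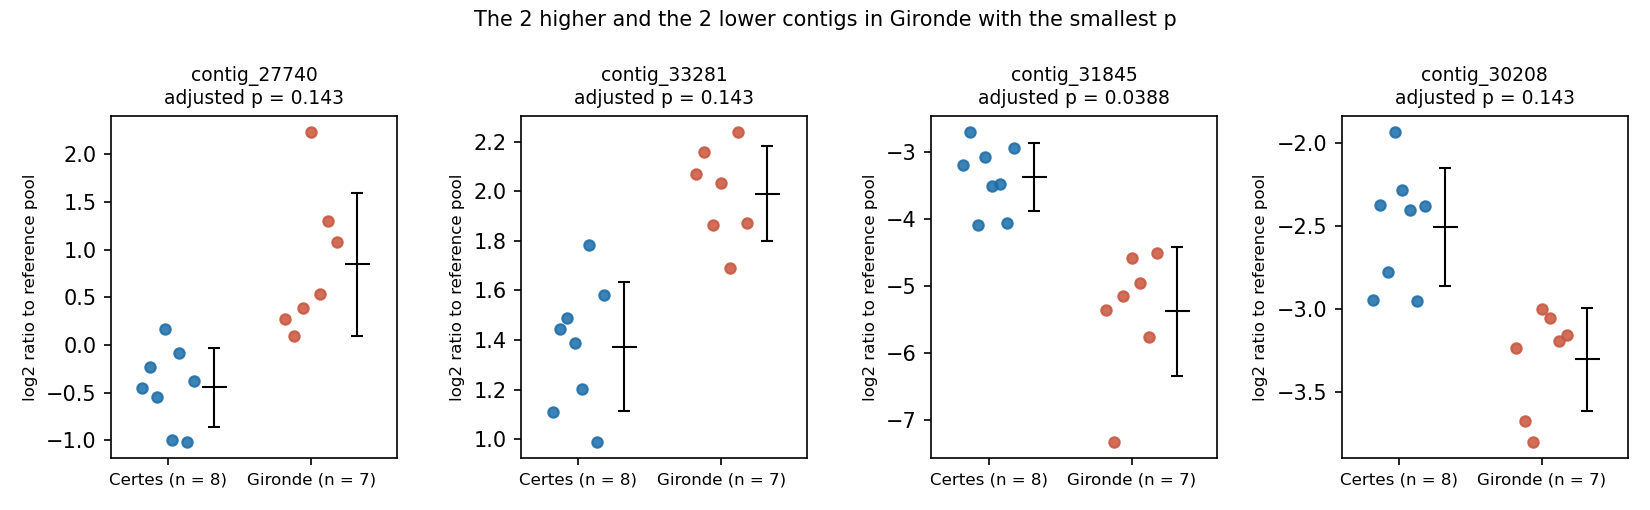
Log2 ratio to the reference pool (y axis) of 4 contigs in each Certes (blue) and Gironde (red) array; each point is 1 array, and the bar gives the mean and SD of the site. Only contig_31845 passed the adjusted threshold, and in it and in contig_30208 the 2 sites did not overlap.

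No other contig passed. Given here are the contig next by p among those lower in Gironde and the first 2 among those higher. contig_30208 was at -3.30 ± 0.31 (SD, n = 7) in Gironde and -2.51 ± 0.36 (SD, n = 8) in Certes, a difference of -0.80 ± 0.19 (SE; limma, adjusted p = 0.143). With arrays scaled to an equal median absolute deviation or SD it was -0.38 or -0.39 (limma, adjusted p = 0.758 and 0.658). contig_27740 was at 0.84 ± 0.75 in Gironde and -0.44 ± 0.41 in Certes, a difference of 1.29 ± 0.29 (SE; limma, adjusted p = 0.143), and with these scalings the difference was 1.32 and 1.28 (limma, adjusted p = 0.38 and 0.179). contig_33281 was at 1.99 ± 0.19 in Gironde and 1.37 ± 0.26 in Certes, a difference of 0.62 ± 0.15 (SE; limma, adjusted p = 0.143), which became 0.40 or 0.39 with the same scalings (limma, adjusted p = 0.67 and 0.523). Like contig_31845, contig_30208, contig_27740 and contig_33281 were dimmer than the median contig in the reference pool (log2 brightness 7.89, 7.52 and 7.78 against 7.95). Their signal above background was not examined here, so the sizes of their differences are uncertain too. Of the 20 contigs with the smallest p, 13 had the higher mean in Gironde and 7 the lower, with differences of 0.49 to 2.10 in size. The 2 contigs contig_31845 and contig_30208 were the only ones whose sites did not overlap. By chance 0.308 contigs would be given on average if every contig had a value on all arrays (0.0311% of contigs). Contigs with empty cells have a higher chance, and this count was not taken over other splits, so an excess was not tested.

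Over all contigs the median size of the difference was 0.20 on the log2 scale, and 16 contigs were over 1 higher and 16 over 1 lower in Gironde. For 72.0% of the contigs the 95% interval of the difference lay within 1 either way, and for the others it was not confined to that range. These intervals are per contig, not adjusted for the number of contigs, and hold for the deposited array scale. As signal above background is unknown here, they do not exclude a larger change in transcript level. At an unadjusted p of 0.05, 96 contigs passed, 45 higher and 51 lower in Gironde, where 49.6 would be given by chance on average. How far a chance count strays from that average depends on how contigs vary together. Which direction held more contigs was not stable: with arrays scaled to an equal SD 40 were higher and 31 lower, and more were higher in 8 of the 15 fits without 1 array. Contigs are not independent: the other 99 of the 100 splits gave between 10 and 203 contigs, and 11 of the 100, the real one included, gave at least 96.

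The direction of these 96 contigs followed their level against the pool. Of those above the pool on average, 40 were higher in Gironde and 4 lower. Of those below it, 5 were higher in Gironde and 47 lower. Level and brightness in the reference pool were themselves related (Spearman's rho -0.35 across contigs), and the 2 were not separated here. In a fit of the contigs above the median brightness alone, 49 passed the unadjusted threshold, 4 higher and 45 lower. With the level taken from Certes arrays 1 to 4 and the difference from Certes arrays 5 to 8, so that no Certes array entered both, Spearman's rho over the 992 contigs was 0.52 and Pearson's r 0.47. With these sets of arrays exchanged, rho was 0.39 and r 0.39. With arrays scaled to an equal median absolute deviation rho was -0.03 and -0.16 in the 2 arrangements, and with equal SDs -0.03 and -0.09.

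**Figure D2:**
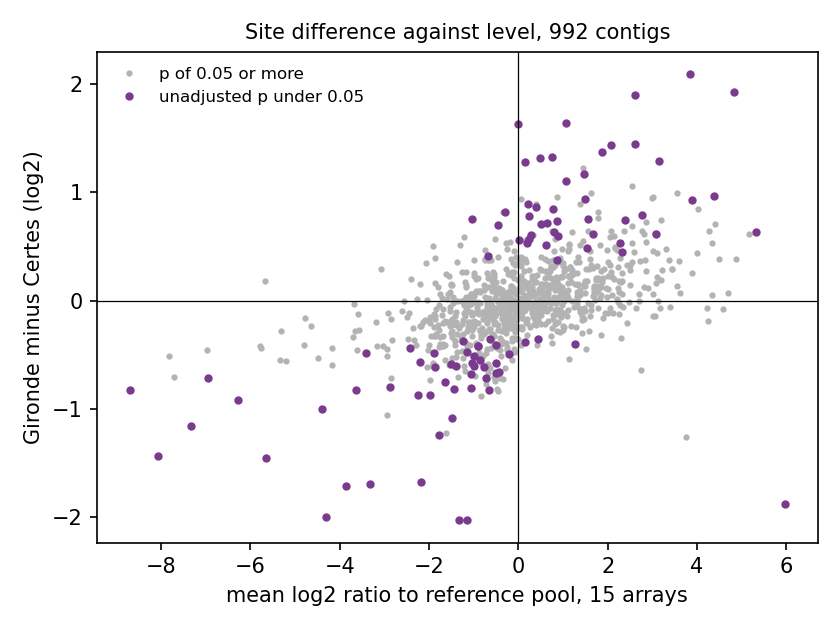
Gironde minus Certes log2 difference (y axis) against the mean log2 ratio to the reference pool over the 15 arrays (x axis); each point is 1 of 992 contigs, purple where the unadjusted limma p was under 0.05. Purple points lie mainly at the upper right (40 contigs) and the lower left (47 contigs).

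Log ratios were wider on the Gironde arrays. The SD of the log2 ratios over contigs was 1.96 ± 0.14 (SD, n = 7) per Gironde array and 1.72 ± 0.16 (SD, n = 8) per Certes array (exact permutation p = 0.00901, 0.018 after Benjamini-Hochberg adjustment over 6 per-array and profile comparisons). The relative difference was 14.1%. Measured by the median absolute deviation, 1.04 ± 0.16 and 0.90 ± 0.11, it was 15.7% but did not pass (exact permutation p = 0.0665, also 0.0665 adjusted). The slope of an array on the mean of the other arrays was 1.06 ± 0.08 in Gironde and 0.94 ± 0.09 in Certes (exact permutation p = 0.0176, 0.0211 adjusted).

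Gironde arrays also differed more from one another than Certes arrays did. The root mean square distance of an array to its site mean was 0.632 ± 0.073 (SD, n = 7) in Gironde and 0.499 ± 0.059 (SD, n = 8) in Certes on the log2 scale, 26.7% larger (exact permutation p = 0.0028, 0.00839 adjusted). With arrays scaled to an equal median absolute deviation the distances were 0.603 ± 0.093 and 0.522 ± 0.041 (exact permutation p = 0.0426, unadjusted). The share of the squared distance between arrays that lay between the sites was 11.7%, against a median of 6.87% over all 6435 splits (exact permutation p = 0.0165, one-sided, 0.0211 adjusted). This test may respond to unequal spread as well as to a shift, and with the same scaling the share was 9.07% (exact permutation p = 0.115).

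Cells without a value were more frequent on Gironde arrays, with 107 of the 121 empty cells against 14 on Certes arrays. The number per array was 15.3 ± 13.3 (SD, n = 7) in Gironde, between 4 and 39, and 1.75 ± 1.04 (SD, n = 8) in Certes, between 1 and 4 (exact permutation p = 0.000311, 0.00186 adjusted). Most of the Gironde cells were on Gironde 4, 6 and 3, with 39, 27 and 17. Gironde 1, 7, 2 and 5 had 9, 6, 5 and 4, near the 4 of Certes 1. The empty cells of both sites fell on 71 contigs, of which 59 were empty on Gironde arrays alone, and no contig was empty on more than 5 arrays.

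**Figure D3:**
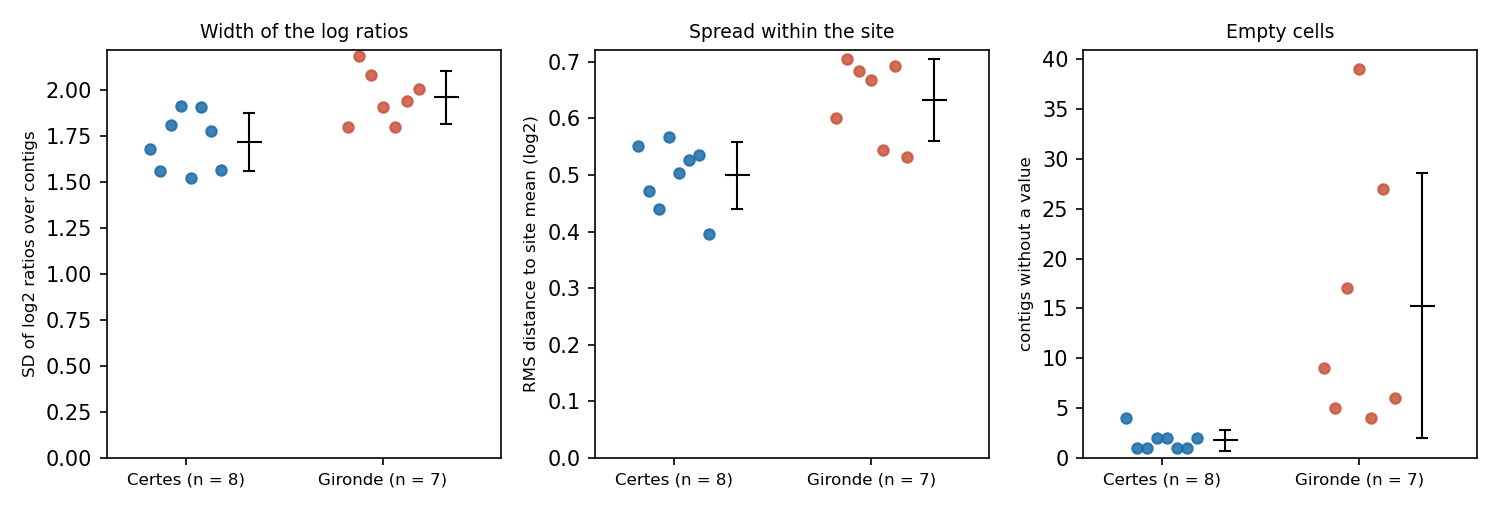
SD of the log2 ratios over contigs (left), root mean square distance to the site mean in log2 units (middle) and number of contigs without a value (right) for each of 8 Certes (blue) and 7 Gironde (red) arrays; bars give the mean and SD of the site. Gironde arrays have the higher mean in each panel, and empty cells reach 39 there against 4 in Certes.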

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

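Of the tests in this part, those of bright contigs, of the middle of the contigs and of single arrays were set out before their results were seen, and those of empty cells and of array scale after. Among 20 sets of values checked for a stray array (10 measures in each site), 1 was found: Certes 1 had 4 empty cells where the other Certes arrays had 1 or 2. Chance marks about 1 in 20 such sets.

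The first pattern is the wider log ratios on Gironde arrays. They did not rest on a few contigs with extreme ratios: over the middle 90% of contigs by level the SD per array was 1.39 ± 0.14 in Gironde and 1.18 ± 0.12 in Certes, a difference of 0.21 (exact permutation p = 0.00777). Whether weak spots in the reference channel widened them stays undecided, since over the brightest 25% of contigs the difference was 0.125, about 7.22% of the Certes value against 14.1% over all contigs (exact permutation p = 0.0985). A biological difference also stays open: the pool came from Certes gonads, so gonads from Gironde may stand further from it. The pool was of wild eels, and the title places the animals in artificial maturation. Distance from the pool may therefore reflect maturation as well as site, and these cannot be told apart here. Labelling or scanning that differed between the sites' arrays cannot be excluded, as no batch is given in the labels.

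The second pattern is the excess of empty cells in Gironde, and neither explanation set against it could be decided. Of the 71 contigs with an empty cell, 65 or 91.6% (95% Wilson interval 82.8% to 96.1%, counting error only) lay among the dimmest 25% of contigs in the reference channel. This shows where empty cells fell and not why Gironde arrays had more, since the same brightness ranking stands for both sites. Of the 69 contigs empty on a Gironde array, 53.6% (95% Wilson interval 42.0% to 64.9%) had a mean above 0 on the other Gironde arrays (46.4% if the ratio ran the other way), but that mean leaves out the arrays without a value and dim contigs of the reference tend to high ratios, so transcripts below detection in Gironde gonads are not excluded. Weaker labelling and higher background on those arrays stay open too.

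The third pattern is the larger spread among Gironde arrays. A single outlying array does not explain it, as the exact permutation p was at most 0.00699 without any 1 of the 15 arrays. The excess over Certes was 26.7% as deposited, 15.6% with equal median absolute deviations and 12.8% with equal SDs. Scaling by width shrinks distances on wider arrays whatever made them wide, so the smaller excess does not show that array scale was a cause. With these scalings the exact permutation p stayed under the threshold by little (at most 0.046). This p is approximate, since site means were not recomputed for each split. It was not adjusted over comparisons there, so whether the excess passes after adjustment was not shown. Weak spots in the reference channel stay undecided, with an excess of 21.4% over the brightest 25% of contigs (exact permutation p = 0.0713). Animals at more varied stages of gonad maturation in Gironde may give the same picture, and no stage per animal was analysed here.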

How the results depend on the processing

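The count of 1 contig past the adjusted threshold became 0 with equal median absolute deviations, with equal SDs (a scaling added after seeing the data), with unequal variances per contig and over contigs above the median brightness of the reference, a set that left contig_31845 out. It was 96 at an unadjusted p of 0.05, ranged from 0 to 1 over the fits without 1 array, and stayed 1 (contig_31845) with array weights, trend and robust settings, complete contigs only (also added) and an adjusted p of 0.1. The lowest adjusted p ranged from 0.0217 to 0.38 over the settings with all arrays and from 0.00852 to 0.116 without 1 array. contig_31845 stayed lower in Gironde in every setting that held it, by -2.14 to -1.67 without 1 array. Without 1 array no other sign was possible, as its sites did not overlap. The 96 contigs at the unadjusted threshold (45 higher, 51 lower) became 72 (34 higher, 38 lower) and 71 (40 higher, 31 lower) under the scalings by median absolute deviation and SD, and ranged from 75 to 137 without 1 array, with more higher than lower in 8 of these 15 fits (45 and 31 without Gironde 2). Over the brighter contigs of the reference 49 passed, 4 higher and 45 lower. The share of squared distance between the sites was 9.07% with equal median absolute deviations and 9.66% with equal SDs (exact permutation p = 0.115 and 0.057, no longer past the threshold), and 10.9% to 14.2% without 1 array. The difference in width between the sites was 0.141 when measured by the median absolute deviation, no longer past the threshold although not smaller in relation to Certes (15.7% against 14.1% by the SD), and 0.205 to 0.27 in SD without 1 array. The differences in spread (0.116 to 0.153) and in empty cells (9.58 to 15.4) kept their direction and side of the threshold without any 1 array. The correlation of difference with level (rho 0.52 and 0.39 in the 2 arrangements) was lost under both scalings, which were run on it after seeing the data: -0.0295 and -0.156 with equal median absolute deviations, -0.0292 and -0.0885 with equal SDs. Giving every array the same width takes out a relation that comes from array scale by construction. The correlation was 0.40 to 0.58 and 0.24 to 0.48 without 1 array. None of the 4 named contigs changed sign, which their choice by smallest p in these same data made likely beforehand. In 100 splits of the 15 arrays, the real one included, 6 gave at least 1 contig past the adjusted threshold (highest other 4) and 11 gave at least 96 past the unadjusted one (highest other 203), so chance is excluded for neither count.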

Other observations

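On the first principal component of the 921 complete contigs, which held 20.3% of the variance, Gironde arrays had a mean score of 4.80 ± 8.63 (SD, n = 7) and Certes arrays -4.20 ± 4.40 (SD, n = 8; exact permutation p = 0.0213, unadjusted). Gironde 2, 3 and 7 stood at 18.0, 11.9 and 9.87, above the Certes range of -9.37 to 5.06. The other 4 Gironde arrays lay within it, Gironde 5 at 2.97, Gironde 4 at -1.996, Gironde 6 at -2.04 and Gironde 1 at -5.15. This score rose with the width of the log ratios on an array, measured by the median absolute deviation, a relation looked at after the scores were seen. Over the 15 arrays Pearson's r was 0.936 and Spearman's rho 0.857 (permutation p = 0.00001, the smallest the number of permutations drawn can give, and 0.00011; 0.00008 and 0.000293 after Benjamini-Hochberg adjustment over 8 relations). Without Gironde 2 and 7, r was 0.884 and rho 0.786 (permutation p = 0.00005 and 0.00243, 0.0002 and 0.00389 adjusted). Within Certes r was 0.833 and rho 0.69 (exact permutation p = 0.00935 and 0.0694, 0.0107 and 0.0694 adjusted), and within Gironde r was 0.971 and rho 0.929 (exact permutation p = 0.000794 and 0.00675, 0.00159 and 0.00899 adjusted). The site difference on this component is therefore not separate from the difference in width.

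The highest correlation of any pair of arrays, 0.957, was between arrays of different sites. Contigs with an empty cell lay further from the pool than complete ones where they had a value, with a median absolute log2 ratio of 1.48 against 0.89. Of these contigs, 65 of 71 were among the dimmest 25% in the reference channel. They were not compared with complete contigs of like brightness, so brightness may account for this difference.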
